A study of Mus musculus with 2 samples.

How the data were processed

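Binding of HA-tagged ZFP488 was profiled by CUT&Tag in 2 libraries of mouse oligodendrocyte precursor cells (OPCs) that had received a lentivirus carrying the tagged protein. In CUT&Tag an antibody directs the Tn5 transposase to the places where the target protein sits, and the transposase cuts and tags the DNA there, so that sequenced fragments pile up at those places. Fragments also come from accessible chromatin and from sequence present in many copies. Libraries were made with a commercial CUT&Tag kit, per the labels' protocols. Each library is 1 replicate of the only group. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical. No control library (untagged cells or a non-specific antibody) was analysed here, and no comparison between conditions was made.

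For each library the deposited values are a list of peak summits, each a 1 bp position with a score. The submitters' processing notes name Bowtie, MACS3 and the mm10 build, without versions or parameters. The deposited peak names carry the word bwa, so which aligner made the lists is not settled. Summits were called on each replicate separately, as the peak names show. The score is the authors' −log10 of a p-value or q-value from the peak caller. Which of these it is, and whether a control or a filter for problem regions was used, is not given in the sources used here. No score lies below 2. Scores depend on depth, so their sizes were not compared between lists. They were used to rank and filter summits within a list, to correlate the replicates over shared summits, and to class shared pairs by the lower of their scores. Read numbers per library are unknown, so no read-based interval or detection floor was computed, and the intervals given below cover counting error of summits only.

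The gene table used was RefSeq for GRCm38.p6, the assembly called mm10 by the submitters. It gives the start and end of each gene, with no strand, exon or sequence. The planned promoter test was therefore run on both ends of each gene, and a "gene end" below is a position within 1 kb of either end of a protein-coding gene. Classes of exon, intron and UTR could not be assigned. The planned test of 31 sequence motifs and the background matched on promoter CpG content were not run. Positions are 1-based mm10 coordinates.

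Summits of the replicates were paired when each was the other's nearest summit and they lay within 200 bp. Chance was taken from 1000 circular shifts of replicate 2 along each chromosome (one-sided permutation test, smallest possible p = 0.001). Scores of shared and unshared summits were compared by the difference of medians with 100000 permutations, two-sided. The midpoints of shared pairs on chromosomes 1 to 19, X and Y were classed as gene end, gene body or between genes, in that order. They were compared with the share of bases in each class between the first and last gene or summit of each chromosome, with an exact binomial test, two-sided. Assembly gaps were not removed from that background. The 19 gene lists, with 519 distinct genes, were tested at gene ends against all other protein-coding genes (Fisher's exact test, two-sided). They were also tested at loci, meaning a summit in the body or within 10 kb of it, against 10000 random lists matched on locus length in 10 classes (permutation test, two-sided). Adjustment was by Benjamini-Hochberg over the 3 classes, the 2 replicates or the 19 lists, with a threshold of 0.05. All list symbols matched a gene, through an older symbol where needed.

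The gene lists, tests, alternatives and rule for naming genes were fixed before the data were examined, with exceptions. Added afterwards were the comparison of gene-end shares between weak and strong shared summits, and the divisions by score of sharing and of place relative to genes. So were those marked in the closing section. For the scores of shared pairs the plan held a Spearman correlation alone. The Pearson correlation and the subset with a lower score under 10 were outside it. The rule named the 25 shared summits with the highest percentile of score in the list where it ranked lower, each with the gene it lies in or the nearest within 50 kb. It also named up to 4 members of each list with a shared summit, and always a short fixed set of genes, which included Zfp488, Olig1, Olig2, Sox10, Myrf, Id2, Id4, Mbp and Pdgfra. Some items that the rule or the tables name are not reported here. Alternatives covered the pairing distance, the score, the gene-end window, the background and each replicate alone. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The pairing and list tests were tested on simulated summits placed on the real gene table. All 600 summits planted as shared were recovered, with 606 pairs called. Their partners were placed well inside the pairing distance, so full recovery was set in advance. The planted list, in which 14 of 28 genes were given a summit, was called by both list tests over 21887 genes. That share is far above that of any list with shared summits in the data, so the power for weaker effects was not examined. The gene-end test called 2 lists in that simulation, the second being the differentiation inhibitors, which hold 2 of the planted genes. The gene-end test called no list in any of 20 sets of randomly placed summits. The test at loci was not run on these sets. They lack the gene-end enrichment and clustering of the real summits, so they say little about false calls there.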

Results

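ZFP488 is a zinc-finger protein of the oligodendrocyte lineage, the cells that make myelin in the brain and spinal cord. The study asked where the protein binds in oligodendrocyte precursor cells, using a version with an HA tag, a short peptide that an antibody recognises. The data were 2 lists of CUT&Tag summits, 1 per replicate. Replicate 1 held 3355 summits in 3155 peaks and replicate 2 held 7142 summits in 6784 peaks, 2.13 times as many summits. The median score was 3.35 in replicate 1 and 3.46 in replicate 2. Most summits scored low, with 76.2% of replicate 1 and 77.8% of replicate 2 below a score of 5. A small set scored very high, with 87 summits of replicate 1 and 91 of replicate 2 at 100 or more, and maxima of 57101 and 39600. On the assembled nuclear chromosomes lay 3256 and 7035 summits, respectively.

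The first comparison asked how many summits were found in both replicates. A total of 634 summits were shared within 200 bp, which was 18.9% of replicate 1 and 8.88% of replicate 2. Circular shifts gave a mean of 19.6 shared summits and a maximum of 44, so the observed number was 32.4 times chance (permutation test, p = 0.001, the smallest possible). The ratio depended on the null and on the sequences included. A shift of 5 kb gave a mean of 23.5 and a ratio of 26.9. On autosomes and X alone, 571 summits were shared against a mean of 3.59 by circular shifts, a ratio of 159, since most chance pairs lay on the other sequences. Of the shared summits, 573 lay on chromosomes 1 to 19, X and Y, 14 on mitochondrial DNA and 47 on unplaced contigs. The remaining 2721 summits of replicate 1 and 6508 of replicate 2 had no partner. The excess over shifts shows that positions recur between the lists. It does not show that ZFP488 binds there, since other recurring signal would give it too and no control library was analysed.

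Sharing depended on the score. In replicate 1, 6.19% (95% exact interval 4.93 to 7.66%) of the 1276 summits scoring 2 to 3 were shared, against 82.1% (76.5 to 86.8%) of the 229 scoring 10 to 100 and 93.1% (85.6 to 97.4%) of the 87 scoring 100 or more. In replicate 2 the shares in the same classes were 2.28%, 62.4% and 93.4%. Of summits scoring 100 or more, 29.9% in replicate 1 and 23.1% in replicate 2 lay on mitochondrial DNA or unplaced contigs. At scores of 10 to 100 these were 6.99% and 6.36%, and at 2 to 3 they were 1.02% and 0.851%. Shared summits had a higher median score than unshared ones, 8.10 against 3.11 in replicate 1 and 8.92 against 3.20 in replicate 2 (permutation test, adjusted p = 1e-05 in each, the smallest possible). Across the 634 shared summits, the log10 scores of the replicates correlated with Pearson r = 0.94 and Spearman rho = 0.79 (permutation p = 1e-04 for each, the smallest possible). Across the 406 pairs with a lower score under 10, r was 0.27 and rho was 0.29. These pairs were cut on the score itself, which narrows its range and can lower a correlation. These correlations are across summits, which are not independent replicates.

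**Figure D1:**
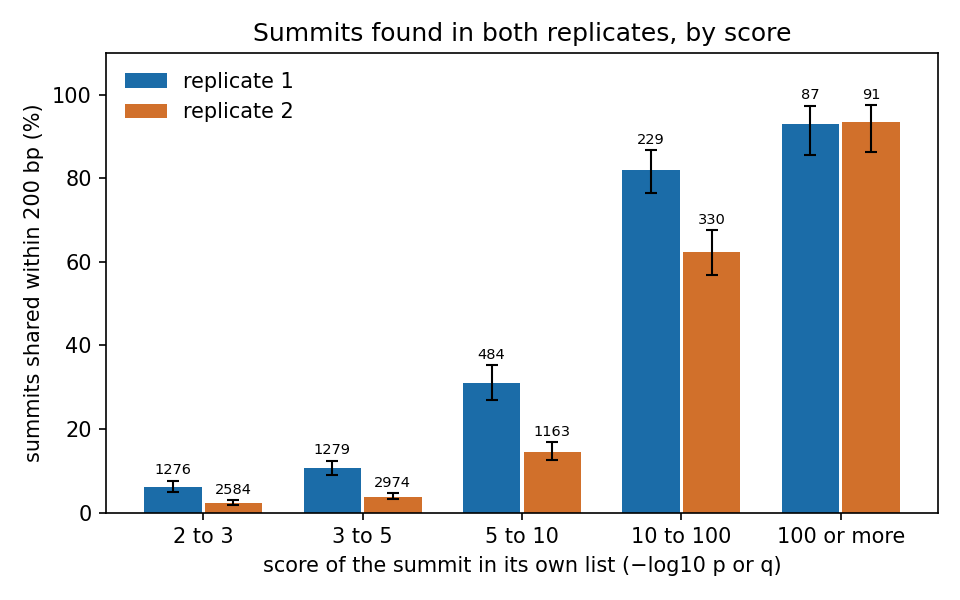
Bars give the percentage of summits in each replicate (y axis) with a partner in the other replicate within 200 bp, by the summit's own score (x axis, −log10 of a p-value or q-value), with 95% exact binomial intervals and the number of summits above each bar. In replicate 1 the share goes from 6.19% at scores of 2 to 3 to 93.1% at scores of 100 or more. Of the latter summits, 29.9% lay on mitochondrial DNA or unplaced contigs.

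Most of the strongest shared summits lay far from protein-coding genes. Of the 25 with the highest ranks, 17 had no protein-coding gene within 50 kb, 1 was on mitochondrial DNA, 6 had a gene within 50 kb and 1 lay inside a gene. The highest was at position 98667122 of chromosome 2 in replicate 1 and 98667123 in replicate 2, with scores of 57101 and 39600, at a distance of 1035450 bp from the nearest protein-coding gene. On chromosome 9, 7 of the 25 fell between positions 3000546 and 3034933, at least 300302 bp from the nearest protein-coding gene. The 6 genes within 50 kb were Tmem196 (7574 bp from a summit with scores of 12220 and 21911), Rpusd4 (29487 bp), Gm14496 (11863 bp), Mrgprd (17085 bp), Gm45871 (8688 bp) and Col19a1 (24805 bp). The only gene to contain one was Cldn34d, on chromosome X, with scores of 733 and 1224. These 25 pairs were placed at nearly the same base in both replicates, with a median offset of 1 bp and a maximum of 19 bp. Among shared summits with a lower score of 3 to 5 the median offset was 71 bp.

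**Figure D2:**
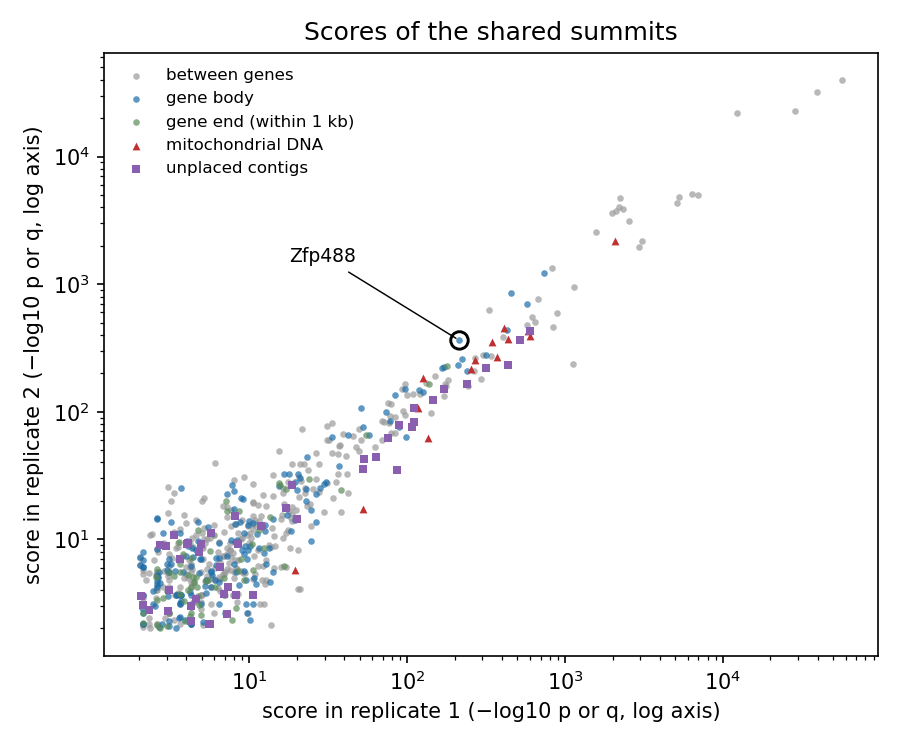
Each point is 1 of the 634 shared summits, with its score in replicate 1 (x axis) and replicate 2 (y axis), both −log10 of a p-value or q-value on log axes, coloured by its place relative to protein-coding genes or by sequence. The circled point is the summit inside Zfp488, with scores of 215 and 362. The highest point lies between genes on chromosome 2, with scores of 57101 and 39600.

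The next comparison asked where shared summits lie relative to genes. Gene ends held 66 of the 573 shared summits on chromosomes, or 11.5% (95% exact interval 9.02 to 14.4%), against 2.93% of bases, a 3.93-fold enrichment (exact binomial test, adjusted p = 2.90e-20). Because summits cluster, the same share was compared with circularly shifted summits, which gave a mean of 3.08% (permutation test, adjusted p = 0.00599, the smallest that 1000 shifts can give after adjustment). Gene bodies away from the ends held 31.2% against 36.6% of bases, or 0.85-fold (exact binomial test, adjusted p = 0.0122). Against shifted summits, with a mean of 38.3%, the deficit was at least as large (0.82-fold). It was not past the threshold in that test (permutation test, adjusted p = 0.0959). All summits of replicate 1 did not differ from bases past the threshold (1.04-fold, exact binomial test, adjusted p = 0.126), and those of replicate 2 lay in gene bodies more often than bases do (1.12-fold, exact binomial test, adjusted p = 7.33e-15). The space between genes held 57.2% against 60.5% of bases (exact binomial test, adjusted p = 0.114). In a division by score added afterwards, without a test, this share differed between weak and strong pairs, so the pooled value averages unlike classes. It was 44.9% at lower scores of 2 to 3, 47.9% at 3 to 5 and 60.8% at 5 to 10. At 10 to 100 it was 66.4% and at 100 or more 74.1%.

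In a comparison chosen after the values were seen, the gene-end share was higher among weak than among strong shared summits. It was 17.4% (44 of 253) for pairs with a lower score under 5 and 3.45% (2 of 58) for pairs scoring 100 or more (Fisher's exact test, p = 0.00654). The test treats summits as independent although they cluster, so its p-value may be too small. Summits found in 1 replicate alone also lay at gene ends more often than bases do, at 13.5% of 2683 summits in replicate 1 (4.59-fold) and 9.94% of 6462 in replicate 2 (3.39-fold).

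**Figure D3:**
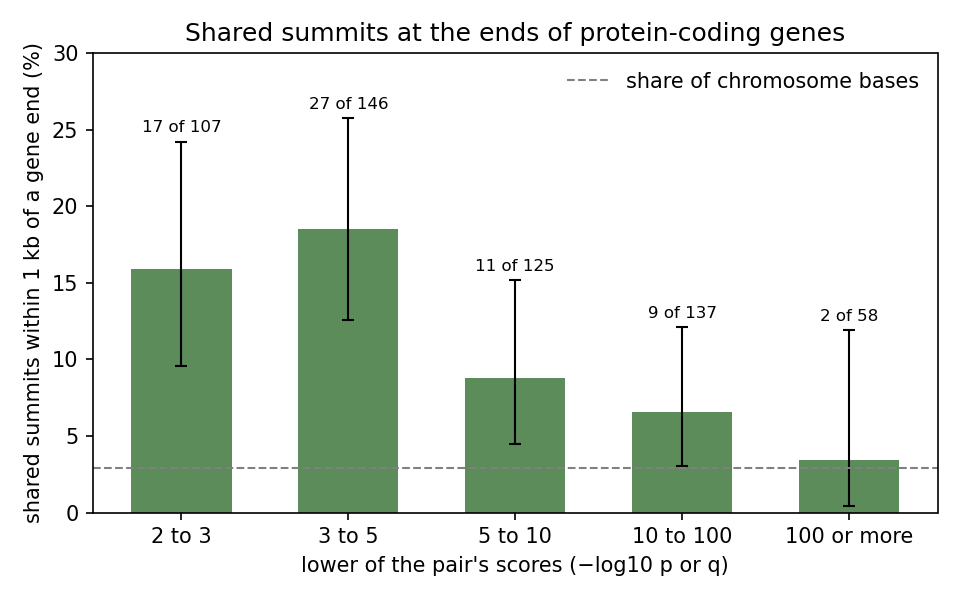
Bars give the percentage of shared summits on chromosomes 1 to 19, X and Y that lie within 1 kb of either end of a protein-coding gene (y axis), by the lower score of the pair (x axis, −log10 of a p-value or q-value), with 95% exact binomial intervals and counts. The dashed line is the share of bases within 1 kb of a gene end, 2.93%, and the bar for scores of 100 or more stands at 3.45%.

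The 66 gene-end summits lay at 74 genes, 0.338% of the 21887 protein-coding genes. Of these genes 12 carry predicted or clone names, and 60 of the other 62 had a summit whose lower score was under 20. The genes named in this paragraph were chosen after their values were seen. By rank, the strongest with other names were Lars2, which encodes the mitochondrial leucyl-tRNA synthetase (137.7 and 165.3), and the double homeobox gene Duxf3 (23.8 and 29.6). Next came 2 summits that stood where the ends of neighbouring genes meet, one at Cdca2 and Kctd9 (12.5 and 8.48) and one at Fancm and Fkbp3 (11.6 and 11.8), then Crlf2 (8.84 and 6.95) and Lnpep (7.199 and 16.5). The highest of all was at Gm32584, a predicted gene (179.1 and 229.9). Values in parentheses are the scores in replicates 1 and 2. Without a repeat annotation or a control library, these scores alone do not show binding of ZFP488.

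The gene lists asked whether shared summits concentrate at genes of the oligodendrocyte lineage, the pathways that restrain its differentiation, or other brain cell types. At gene ends, 17 of the 19 lists had no member with a shared summit. These included the lists of OPC markers (20 genes), lineage transcription factors (31), myelin genes (30), the Wnt pathway (38), the BMP and TGF-beta pathway (35), the Notch pathway (28), Polycomb and histone deacetylase subunits (36), and markers of neurons, astrocytes, microglia and endothelial cells. The list of immediate early genes, which respond quickly to stimulation, had 2 of 24 members, Nr4a3 (4.61 and 5.11) and Egr1 (4.50 and 3.23). Its odds ratio was 27.5 (Fisher's exact test, p = 0.00297, adjusted p = 0.0564), short of the threshold. With all summits of 1 replicate, lists that hold these genes by construction, the odds ratio was 4.08 in replicate 1 (Fisher's exact test, adjusted p = 0.914) and 3.91 in replicate 2, where Jun was added (Fisher's exact test, adjusted p = 0.325). No member was left at scores of 5 or more in both lists. Egr1 was also the single member of the list of differentiation inhibitors with such a summit (Fisher's exact test, adjusted p = 0.742). No list passed the threshold by either test, and 1 list did so before adjustment in each. With so few gene-end summits the test had little reach, since a list of 28 genes would have needed 3 members to pass at the strictest step of the adjustment.

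In the gene body or within 10 kb of it, 10 of the 519 list genes had a shared summit. By the same rule 310 of all 21887 protein-coding genes did (1.42%), so a count of this size is not in itself a result about the lists. The 3 highest scores were inside genes, at Smo, the Hedgehog signal transducer (428 and 439), Zfp488 itself (215 and 362) and Jarid2, an accessory subunit of Polycomb repressive complex 2 (98.2 and 63.7). The stronger of the 2 Smo summits lay 12655 bp and the Jarid2 summit 51947 bp from the nearest end of the gene. Smo was the only one of 15 Hedgehog genes with a shared summit, against 0.289 in matched lists. Jarid2 was the only one of 36 Polycomb and histone deacetylase genes, against 0.560. Without a repeat annotation or a control library, these scores do not show binding of ZFP488. The others were Anpep, a pericyte marker (9.87 and 13.0), the tight-junction myelin gene Cldn11 (3.81 and 7.35), the Wnt ligand Wnt7a (4.30 and 3.004), the TGF-beta receptor Tgfbr2 (2.57 and 3.99), the ribosomal protein gene Rps18 (4.21 and 3.83), and Nr4a3 and Egr1. The summit near Rps18 lay inside another gene, Vps52. Against lists matched on locus length, the smallest adjusted p was 0.859 (permutation test), for the immediate early genes.

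Of the genes that were always to be reported and are named here, only Zfp488 had a shared summit within 10 kb. Olig1, a lineage transcription factor, had a summit in replicate 1 alone (score 5.18), and its neighbour Olig2 had 2 in replicate 2 alone (highest 4.72). Sox10 and Myrf, which drive myelin gene expression, had 2 summits each in replicate 1 alone, with highest scores of 5.77 and 2.41. Id2, an inhibitor of differentiation, had 1 in replicate 2 alone (3.32). Mbp, which encodes myelin basic protein, had 1 in each replicate (2.05 and 2.50), and these were not a shared pair. Id4 and Pdgfra had none in either list. Of replicate 1 summits scoring 5 to 10, 31.0% were shared, and of those scoring 2 to 3, 6.19%, so a summit in 1 list alone, or none, does not settle whether the site is bound.

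In each replicate taken alone, no list passed the threshold at gene ends or at loci. The smallest p-values at loci were in the lineage lists. The matching used 10 length classes, the longest without an upper limit, so the longest genes were matched only roughly. In replicate 2, 12 of 20 OPC markers had a summit in the body or within 10 kb, against 6.14 in matched lists (permutation test, p = 0.00740, adjusted p = 0.141), among them Sox5 (18.01), Xylt1 (5.65) and Pcdh15 (5.50). In replicate 1 it was 6 of 20 against 3.33 (permutation test, adjusted p = 0.932). In replicate 1, 10 of 31 lineage transcription factors had one, against 4.01 in matched lists (permutation test, p = 0.00700, adjusted p = 0.133), among them Zfp488 itself, Sox10 (5.77) and Tcf4 (5.69). Zfp488 counts towards this although its summit may come from the lentiviral vector, and the test was not run without it. In replicate 2 it was 9 of 31 against 7.65 (permutation test, adjusted p = 0.988). The Wnt pathway had 16 of 38 in replicate 2 against 9.46 (permutation test, adjusted p = 0.217) and 6 against 4.97 in replicate 1. At gene ends in replicate 2, 4 of 25 genes of cholesterol biosynthesis had a gene-end summit, namely Cyp51, Dhcr7, Mvd and Hmgcs1 (16.0% against 3.52% of other genes, Fisher's exact test, adjusted p = 0.206). In replicate 1 the list had 1 such gene, Insig1. The list of differentiation inhibitors had 3 of 24 in replicate 2, Sox2, Sox6 and Egr1 (Fisher's exact test, adjusted p = 0.325), and Egr1 alone in replicate 1. The Hedgehog list had Hhip and Gli1 in replicate 1 (Fisher's exact test, adjusted p = 0.790) and none in replicate 2.

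The Zfp488 gene itself (NCBI Gene 382867, chromosome 14, positions 33967070 to 33979034) held a high-scoring summit in both replicates. It was at position 33970770 with a score of 215 in replicate 1, and at 33970807 with a score of 362 in replicate 2. These scores ranked 60 of 3355 and 42 of 7142 in their lists. The summits lay 3700 and 3737 bp inside the lower end of the gene and more than 8 kb from the other end. No other summit was found within 50 kb of the gene in either replicate. Among the 226 shared summits inside protein-coding genes it ranked 8. The cells carry a vector with a Zfp488 sequence, and fragments from it would align to the gene where the sequences match.

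**Figure D4:**
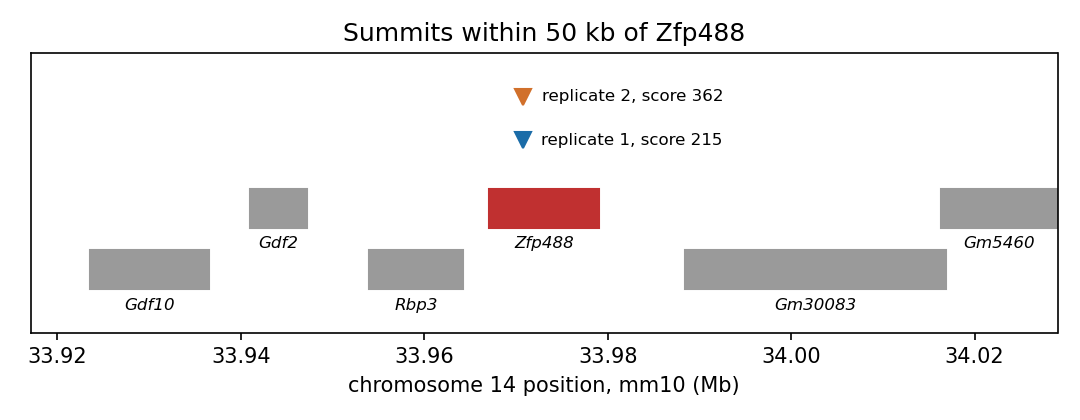
Map of chromosome 14 (mm10, x axis in Mb) around Zfp488 with the protein-coding genes of the RefSeq table as boxes and the summits of replicates 1 and 2 as triangles with their scores. The only summits within 50 kb are at 33970770 and 33970807, inside Zfp488.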

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

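All tests weighed in this part were chosen after the values were seen. Signal was found on sequences that the comparisons with genes did not use. Mitochondrial DNA held 18 summits in replicate 1 and 16 in replicate 2, and unplaced contigs held 81 and 91. The lists hold called peaks only, so these counts do not show whether the signal there is unusual.

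Of the 25 shared summits with the highest ranks, 17 had no protein-coding gene within 50 kb. Of the others, 1 lay inside Cldn34d and 1 within 1 kb of the pseudogene Gm10222. A candidate explanation is sequence present in many copies that the assembly holds in few places, where reads pile up whatever protein is targeted. Mitochondrial DNA, which is multi-copy and outside the nucleus, made up 11 of 77 shared summits scoring 100 or more and 1 of 406 scoring under 10 (Fisher's exact test, p = 9.38e-09), as that explanation needs. The test covers the mitochondrial summits only, since no repeat annotation was used here. It counts each summit as independent, but the mitochondrial summits lie on 1 sequence and other strong summits cluster. Its p-value therefore does not measure evidence from separate sites. Binding of ZFP488 to such sequence stays open, because there is no control library here, and no biological explanation was tested.

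Most summits were in 1 replicate alone. The larger list of replicate 2 as the whole cause is argued against, since only 23.9% of replicate 1 summits (95% exact interval 22.5 to 25.4%) had a partner within 1000 bp. Summits close to the calling threshold are a candidate explanation. Of replicate 1 summits, 82.1% scoring 10 to 100 were shared, against 6.19% scoring 2 to 3. A difference in antibody yield or cells between the replicates was not tested.

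The summit inside Zfp488 was 3700 bp from the nearest end of the gene, which argues against signal at an annotated end. The vector's Zfp488 coding sequence may be the source, with 1 summit within 50 kb in each replicate, but the gene table has no exons, so this cannot be told apart from binding inside the gene. The offset between replicates was 37 bp, and 2 of the 58 shared summits on chromosomes scoring 100 or more, this one included, were offset by as much (median 4 bp). A genome annotation with exons would show whether the site is in coding sequence.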

How the results depend on the processing

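The alternative that kept only autosomes and X with scores under 100 was chosen after seeing the data. The number of shared summits exceeded chance under every alternative run (permutation p = 0.001 in each). It was within 1.5 times of 634 except at a distance of 50 bp (363) and with a score of 5 or more in both lists (359), which by construction admit fewer pairs. On autosomes and X it was 571 against 3.59 by chance, so most chance pairs came from the other sequences, and 504 with scores under 100. A score of 5 or more left 800 summits in replicate 1 and 1584 in replicate 2. The gene-end enrichment stayed past the threshold throughout, from 1.89-fold with a 5 kb window to 5.24-fold with 500 bp, and was 2.35-fold with scores of 5 or more and 4.23-fold without the highest scores. The gene-body deficit was no longer past the threshold with a 500 bp gene-end window (0.90-fold) or against shifted summits. Against shifted summits it was 0.82-fold, at least as large as against bases (0.85-fold). The direction of the gene-body difference was the opposite in each replicate alone (1.04 to 1.12-fold), past the threshold in replicate 2 only. The space between genes fell past the threshold within 500 bp pairing (0.91-fold), with a 5 kb gene-end window (0.90-fold) and in each replicate alone (0.807 to 0.81-fold). The wider window takes bases from the other classes by construction, but in the background too, where between-gene bases fell from 60.5% to 56.3%. The cause of these changes was not tested, but the mix of scores differs between the sets, as shared summits score higher. Among all summits on chromosomes, the gene-body share was lower at high scores. In replicate 1 it was 40.3% at 2 to 3 and 21.3% at 100 or more, and in replicate 2 it was 42.4% and 24.3%. Scores of shared summits stayed above unshared ones at 50 bp and 500 bp. No gene list passed under any alternative run, with smallest adjusted p from 0.0549 to 1. No paired analysis was possible because there is 1 group. The motif test and the CpG-matched background were not run. Read depth is unknown, and the few shared gene-end summits limit the list tests.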

Other observations

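The tests in this part were chosen after the values were seen, apart from the comparison of small RNA classes, which was set before its values were seen. Shared summits also gathered at snRNA genes, snoRNA genes and pseudogenes. Signal there can come from sequence in many copies or from accessible chromatin without ZFP488, and these sources were not separated here. Within 1 kb of snRNA genes lay 14 of the 573 shared summits on chromosomes, against 0.447 by circular shifts (31.3-fold, permutation test, adjusted p = 0.00799 over 8 gene classes), and the ratio was 9.31 over all summits of replicate 1 and 6.55 over those of replicate 2. For snoRNA genes there were 10 (17.7-fold, permutation test, adjusted p = 0.0213) and for pseudogenes 29 (2.90-fold, adjusted p = 0.00799). Over all summits of replicates 1 and 2 the ratios were 7.29 and 4.63 for snoRNA genes and 1.67 and 1.499 for pseudogenes. By the same permutation test, for rRNA genes there were 2 (adjusted p = 0.0519), for tRNA genes 1 (adjusted p = 0.274), for miRNA genes 2 (adjusted p = 0.272) and for lncRNA genes 79 (1.46-fold, adjusted p = 0.0767). Protein-coding genes with their flanks held 245 (1.03-fold, permutation test, adjusted p = 0.731).

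Of the 14 snRNA and 10 snoRNA summits, 8 and 10 came from 1 group of neighbouring genes each. The U3 snRNA genes Rnu3b1 to Rnu3b4, whose RNA takes part in ribosomal RNA processing, lie between positions 87443237 and 87471582 of chromosome 11, and 8 shared summits were within 1 kb of one of them, with scores from 3.79 to 26.9. The snoRNA genes from Gm23953 to Snord116l17 on chromosome 7 (59736313 to 59861824) had 10 shared summits within 1 kb of one of them, with scores from 3.56 to 38.8. The 5S rRNA genes n-R5s117 and n-R5s136 on chromosome 8 had 1 each. The pseudogenes Gm10222 and Gm10925 on chromosome 1 (24612404 to 24614651), the latter listed with the mitochondrial gene name mt-Atp6 among its synonyms, had 4 within 1 kb, with scores from 389 to 894.

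Gene-end summits may favour sites where the ends of 2 genes meet. Of the 66 shared ones, 13 (19.7%, 95% exact interval 10.9 to 31.3%) lay within 1 kb of the ends of 2 or more genes, against 7.34% of gene-end bases (exact binomial test, p = 0.000915). Summits found in 1 replicate alone gave 16.9% of 361 in replicate 1 (p = 1.63e-09) and 14.6% of 642 in replicate 2 (p = 2.79e-10), by the same exact test. Accessible promoters shared by gene pairs would give the same pattern without ZFP488, and a control library would be needed to separate them.

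Chromosome X held 0.515 summits per Mb in replicate 1 and 0.872 in replicate 2, which was 0.397 and 0.310 of the autosomal density. Chromosome Y held 4 and 8 summits. The number of X copies in the cells and the gene density were not taken into account, so these values do not show that ZFP488 avoids X.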
